A study of Mus musculus with 12 samples.

How the data were processed

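Small RNA was sequenced from 12 populations of C57BL/6 mouse cells, with 1 library per population. Per the labels' protocols, total RNA was extracted, RNA of 19 to 24 nt was taken from a gel, and adaptors were ligated only to molecules with a 5' phosphate and a 3' hydroxyl. The deposited tables list each distinct sequence with the miRNA it was assigned to, its length, its position and its read count, which is a raw count with no normalisation per the file headers. A first table per library holds sequences assigned to mature miRNAs, and a second, deposited for 11 libraries here, holds remaining sequences assigned to precursor hairpins. No second table of CD4SP was used here. In CD8SP the names in the 2 tables were those of the opposite kind, so the tables of that library were taken by the names they hold. The adaptor trimming, the aligner, the miRNA release and the number of mismatches allowed are not given in the sources used here.

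Counts were summed per miRNA name over the mature tables. A sequence assigned to several names was split equally among them and counted once in the library total. Values are RPM, reads per 1000000 reads assigned to mature miRNAs. The report gives the total of each library. The totals ran from 63386 reads in DN4 to 4572864 reads in DN3, so that a count of 0, taken as 3 counts per library, stands for up to 47.3 RPM in DN4 and 0.656 RPM in DN3. Sequences were matched to the miRNA hairpins of GENCODE M21 (mouse GRCm38) to give positions and the annotation at them, for 265 of the 276 names that reached 100 RPM in at least 1 library.

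With 1 library per population no test between populations was possible, and no p-value across miRNAs is given. For each pair of libraries the ratio of RPM values was given with its exact 95% conditional binomial (Clopper-Pearson) interval, and single values with exact 95% Poisson intervals. PCR reads are not independent molecules, so all intervals and floors cover counting error only. A miRNA is called higher or lower when the whole interval lay beyond 2-fold and the higher library had at least 100 RPM and 10 reads. Named miRNAs were those with at least 1000 RPM and 30 reads in the higher library that passed this rule, the 8 largest ratios in each direction, together with the 5 most abundant miRNAs of each library and up to 4 members of highest mean of each list. For the thymic range they were the 10 widest with at least 1000 RPM at the highest stage, and for MEF the 8 highest and 8 lowest by ratio to the nearest blood library. The lists were a progenitor list, the miR-181 family, a mature lymphocyte list, the miR-17 cluster and its paralogs, the let-7 family, miR-15 and miR-16, the miR-23, miR-27 and miR-24 clusters, the miR-30 family, an activation list, the miR-183 cluster, the Dlk1-Dio3 locus, the Sfmbt2 repeated cluster and the pan-blood miR-142. Markers of other cell types were myeloid, erythroid, endothelial, epithelial, mesenchymal, muscle, liver and neural miRNAs. A list's median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression. The comparisons, lists, rules and alternatives were fixed before the data were examined, except where the text says otherwise.

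The rule was tested on simulated counts of 548 miRNAs, of which 200 were changed, in 20 runs. At the depths of CD4SP and CD8SP it called 100% of tested miRNAs changed 3-fold and 0% of those not changed. At the depths of DN3 and DN4 it called 65.7% of those changed 3-fold, 88.8% of those changed 6-fold and 0% of those not changed. The true ratio lay inside the interval for 94.0% to 96.9% of tested miRNAs. Counts were drawn as Poisson counts and compared at their true totals, which is the model behind the intervals. PCR, variation between libraries and shifts in scaling were left out, so the simulation gives no rate of false calls for the real libraries.

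Alternatives were median-of-ratios size factors (DESeq2 1.42.0), TMM factors (edgeR 4.0.16), a total without the 3 most abundant miRNAs over all libraries (miR-16, miR-20a and miR-21), shared sequences counted in full or left out, sequences seen once left out, both tables added by miRNA number with the arms together, perfect matches only, other floors, libraries thinned to the shallowest, and rules of 1.5-fold and 4-fold. Each library was left out in turn of the marrow and thymus comparison and each stage of the thymic range, whose lowest stage was taken by its RPM or, as an added alternative, after zeros were set to the floor, list medians were taken with a prior count added or with the more abundant arm only, and correlations and hairpin-table shares were taken in other forms. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3.

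The libraries differed in how their reads begin. In 8 libraries (LSK, MPP, LMPP, ProB, DN1, DN2, CD4SP and CD8SP) between 96.3% and 98.6% of mature reads began at base 3 of the mature miRNA. In DN4, DP and MEF between 96.3% and 98.4% began at base 2, and in DN3 98.8% began at base 1. The most common read length was 20 nt in the libraries beginning at base 3 and 21 or 22 nt in the others. No label gives the cause. The share of a miRNA's reads in the hairpin table also differed between libraries, as for miR-92a, with 97.6% of its reads there in DN2 and 31.3% in DN3, and the cause was not tested. Comparisons of libraries with different read starts carry these differences together with the difference between cells, and are named as such. Comparisons of DN2 with CD4SP and CD8SP, of MEF with DN4 and DP alone, those restricted to 1 read start, and counts without miRNAs that have most of their reads in a hairpin table were added after seeing the data.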

Results

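MicroRNAs were counted in 11 sorted blood-cell populations that follow T cell development in the mouse and in 1 library of embryonic fibroblasts (MEF). The marrow libraries were the lineage-negative Sca+ Kit+ fraction (LSK), its CD135+ CD106+ part (MPP), its CD135+ CD106- part (LMPP) and pro-B cells (ProB). The thymus libraries were the CD4- CD8- stages DN1 to DN4, the CD4+ CD8+ stage (DP) and the mature CD4 and CD8 single-positive cells (CD4SP and CD8SP). Mature miRNA reads numbered 1782770 in LSK, 1901499 in MPP, 979219 in LMPP, 2556026 in ProB, 3754351 in DN1, 2410114 in DN2, 4572864 in DN3, 63386 in DN4, 523881 in DP, 4497420 in CD4SP, 2660370 in CD8SP and 308688 in MEF. Levels are reads per 1000000 mature reads (RPM). Values with the mature and hairpin tables added are of a whole miRNA, with its arms together. There was 1 library per population, so no difference has a replicate check, and the intervals (95%, given in parentheses) cover counting error only.

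miR-21 was the most abundant miRNA in LSK (10.3% of mature reads), MPP (9.98%) and DN1 (15.9%), and miR-20a, of the proliferation-associated miR-17 cluster, in LMPP (9.84%). miR-16 led in ProB (14.7%), DN2 (15.6%), DN3 (12.3%), CD4SP (24.6%) and CD8SP (20.1%). miR-181a, known to set T cell receptor sensitivity, led in DN4 (22.0%) and DP (55.3%), and miR-22 led in MEF (51.7%). The other miRNAs among the 5 most abundant of a blood-cell library were let-7a, let-7f, let-7i, miR-24, miR-93, miR-139-5p, miR-29b, miR-150, miR-15b, miR-142-3p, miR-142-5p and miR-378.

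**Figure D1:**
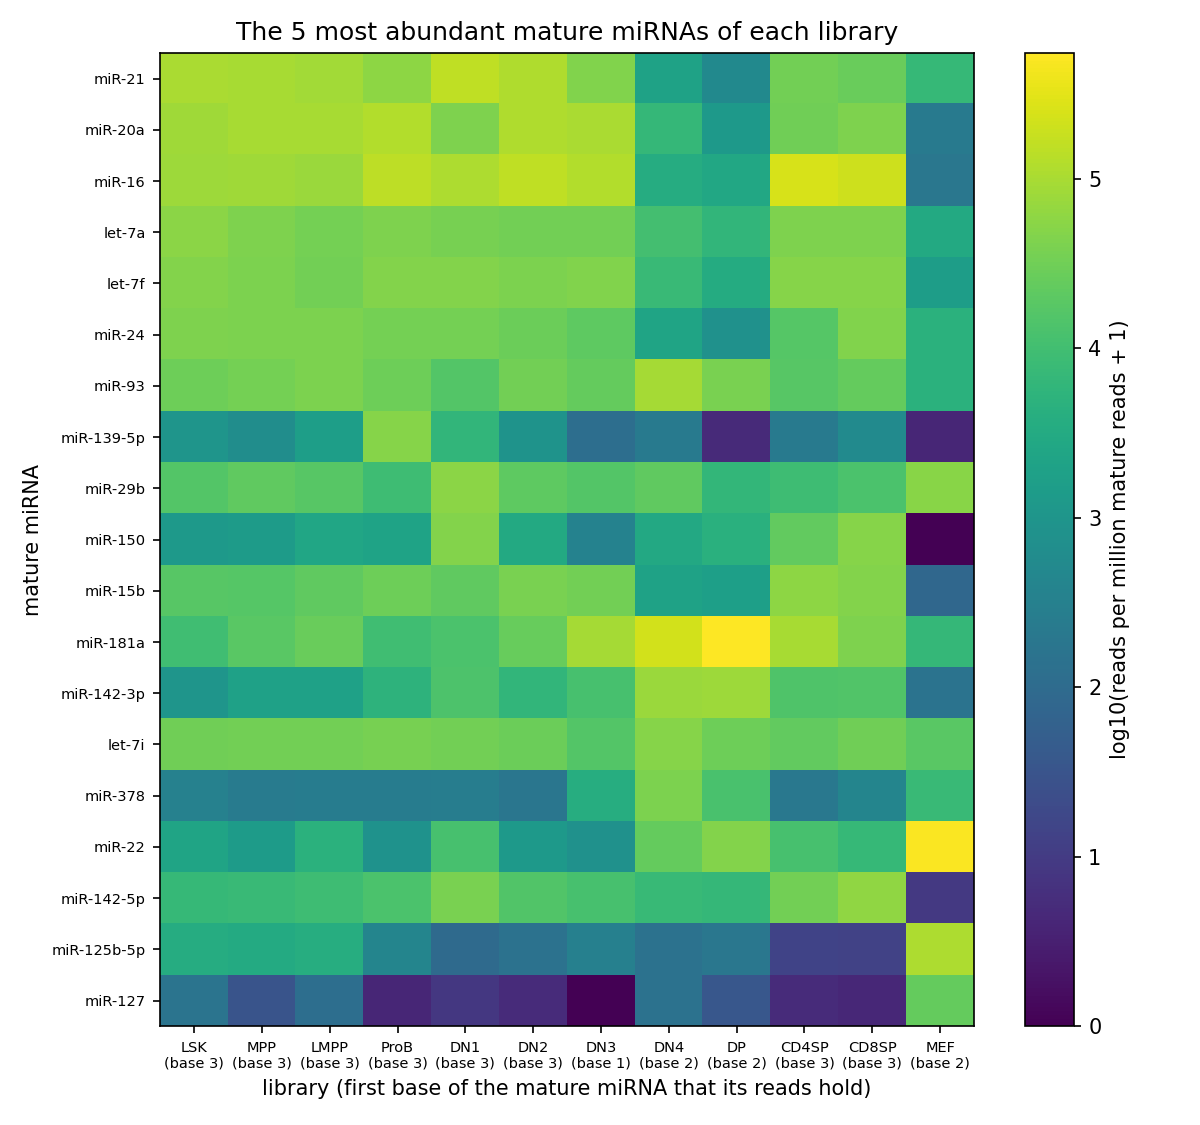
RPM (colour, log10 of the value + 1) of the miRNAs that are among the 5 most abundant of any of the 12 libraries, with the first base that the reads of each library hold. miR-181a took 55.3% of the reads of DP and miR-22 took 51.7% of those of MEF.

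How the marrow progenitors differ among themselves was asked first, with LSK and MPP, both with reads from base 3. Of 140 miRNAs tested, 3 were lower in MPP and 0 higher. Those 3 were miR-541 (10.7-fold lower, 7.36 to 16) and miR-127 (5.56-fold, 4.17 to 7.54), the measured members of the imprinted Dlk1-Dio3 locus, and the red-cell miRNA miR-486 (2.62-fold, 2.37 to 2.90); they lie below the level set for naming and were picked after their values were seen, and miR-486 did not pass the rule with the libraries thinned to the shallowest. The miR-181 family had a median log2 ratio of 0.73, at percentile 99.97 of matched lists, although 0 of its 5 members passed the rule.

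From MPP to LMPP, 14.8% of the miRNAs tested were apart, 21 higher and 2 lower in LMPP. Higher were miR-342-3p (3.77-fold, 3.46 to 4.11), the 1 of 7 mature lymphocyte members to pass the rule, miR-128 (3.37-fold, 3.16 to 3.59), miR-22 (3.24-fold, 3.09 to 3.40) and miR-139-5p (2.5-fold, 2.32 to 2.70). The liver miRNA miR-122 (3.49-fold, 3.32 to 3.68) and the red-cell miRNAs miR-451 (3.02-fold, 2.86 to 3.18) and miR-486 (3.64-fold, 3.28 to 4.04) were higher too. miR-2142 had 1504 RPM in LMPP and 7.89 in MPP, a ratio of 190.7 (115.2 to 341.6). The 2 lower ones were miR-130a, of the progenitor list (2.38-fold, 2.27 to 2.49), and miR-31 (3.36-fold, 2.93 to 3.88), which was named after its value was seen. Of 14 members of the progenitor list 1, miR-10b (3.46-fold, 2.64 to 4.59), was higher and 1 lower, and of the Dlk1-Dio3 locus 2 of 2, miR-127 and miR-494, were higher. Of the mesenchymal miRNAs, miR-143 stood at 344.2 RPM in LMPP against 40.5 (8.50-fold, 6.62 to 11.03), miR-199a-3p, which shares its reads with miR-199b, at 198.1 against 64.7, miR-199a-5p at 36.8 against 8.41 and miR-214 at 20.4 against 5.78, while miR-31, miR-322 and miR-503 were at 241.0, 7753 and 698.5 RPM against 810.9, 11630 and 991.3. In the miR-181 family 1 of 5 members, miR-181a-1*, was higher (median log2 ratio 0.52, percentile 99.8); miR-10b, miR-127, miR-494, the mesenchymal miRNAs and miR-181a-1* were named after their values were seen. The activation list had a median log2 ratio of -0.45 (percentile 0.995) with 0 of 5 members passing the rule. Size factors shifted all log2 ratios by -0.17 and TMM factors by -0.28, and miR-127, miR-494 and miR-181a-1* passed the rule with neither and miR-139-5p (2.06-fold) not with TMM factors. miR-494 did not pass it without sequences seen once, nor did miR-127, miR-494, miR-181a-1*, miR-139-5p, miR-10b or miR-130a with the libraries thinned to the shallowest.

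Entry to the B lineage was examined from LMPP to ProB, again between libraries with reads from base 3. miR-139-5p stood at 51029 RPM in ProB against 1630 (31.3-fold, 29.8 to 32.9), followed by miR-34a (5.96-fold, 5.43 to 6.56), miR-20b (2.98-fold, 2.88 to 3.08) and miR-106a (2.97-fold, 2.88 to 3.07). All 13 measured members of the progenitor list were lower, with a median log2 ratio of -3.04 (percentile 0.02). Among them miR-196b was 31.9-fold lower (30.4 to 33.5), miR-125a-5p 19.0-fold (17 to 21.3), miR-222 18.3-fold (15.9 to 21.3), miR-221 15.2-fold (14.55 to 15.9) and miR-10a 8.25-fold (7.90 to 8.62). The myeloid miR-223 was 157.6-fold lower (135.2 to 184.7), miR-122 151.0-fold (119.8 to 193.03), miR-451 67.6-fold (56.8 to 81.1) and miR-486 42.8-fold (33.1 to 56.1). miR-484 was 2.28-fold higher (2.10 to 2.48). miR-142-3p, which marks all blood cells, was 2.67-fold and miR-128 2.41-fold higher in the mature tables. With both tables added the ratio of miR-128 was 1.98, not past the rule, and that of miR-142, with both arms together, 1.78. In all, 12 of 157 miRNAs were higher and 48 lower in ProB. TMM factors, which shifted all log2 ratios by 0.70, gave 37 higher and 33 lower, and size factors (0.41) 27 and 36; without the 3 most abundant miRNAs the shift was 0.13. miR-128 and miR-484 did not pass the rule with the libraries thinned to the shallowest.

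LMPP and DN1 were set against each other to see what changes between marrow progenitors and the earliest thymic stage sampled. The progenitor list was lower for 13 of 13 members (median log2 ratio -3.33, percentile 0.015). miR-125b-5p was 38.7-fold lower (34.8 to 43.3), miR-99a 36.6-fold (33.1 to 40.7), miR-196b 34.4-fold (33.0 to 35.9), miR-130a 25.1-fold (22.5 to 28.2), miR-126-5p 16.9-fold (15.1 to 19.0) and miR-126-3p 13.3-fold (13.0 to 13.7). Of the mature lymphocyte list, 8 of 9 measured members were higher and 1, miR-146b, lower (median log2 ratio 1.93, percentile 99.98). miR-150 was 18.2-fold higher (17.5 to 19.0), miR-146a 6.68-fold (6.28 to 7.11), miR-342-3p 5.28-fold (5.01 to 5.56), miR-29c 3.57-fold (3.21 to 3.99) and miR-29b 3.01-fold (2.96 to 3.06). Alongside them the myeloid miR-223 was at 17609 RPM in DN1 and 10296 in LMPP, and the epithelial miR-141 and miR-200c were at 290.7 and 253.8 in DN1 and 49.0 and 45.4 in LMPP. Erythroid miRNAs summed to 835.3 RPM in DN1 and 4655 in LMPP, and mesenchymal ones to 2261 and 10105, with miR-322 alone at 1630 and 7753. Both arms of miR-142 were higher, miR-142-3p 6.97-fold (6.66 to 7.30) and miR-142-5p 4.31-fold (4.22 to 4.40), as was miR-139-5p (3.75-fold, 3.57 to 3.95). miR-122 was 736.0-fold lower (485.4 to 1176) and miR-2142 71.5-fold (57.0 to 90.8), or 160.4-fold with both tables added. Of 158 miRNAs, 15 were higher and 60 lower in DN1. TMM factors (shift of 0.61) gave 27 higher and 34 lower, and size factors (0.56) 25 and 36. miR-146b did not pass the rule with either (1.76-fold and 1.82-fold lower), nor did miR-146b or miR-29c with the libraries thinned to the shallowest.

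**Figure D2:**
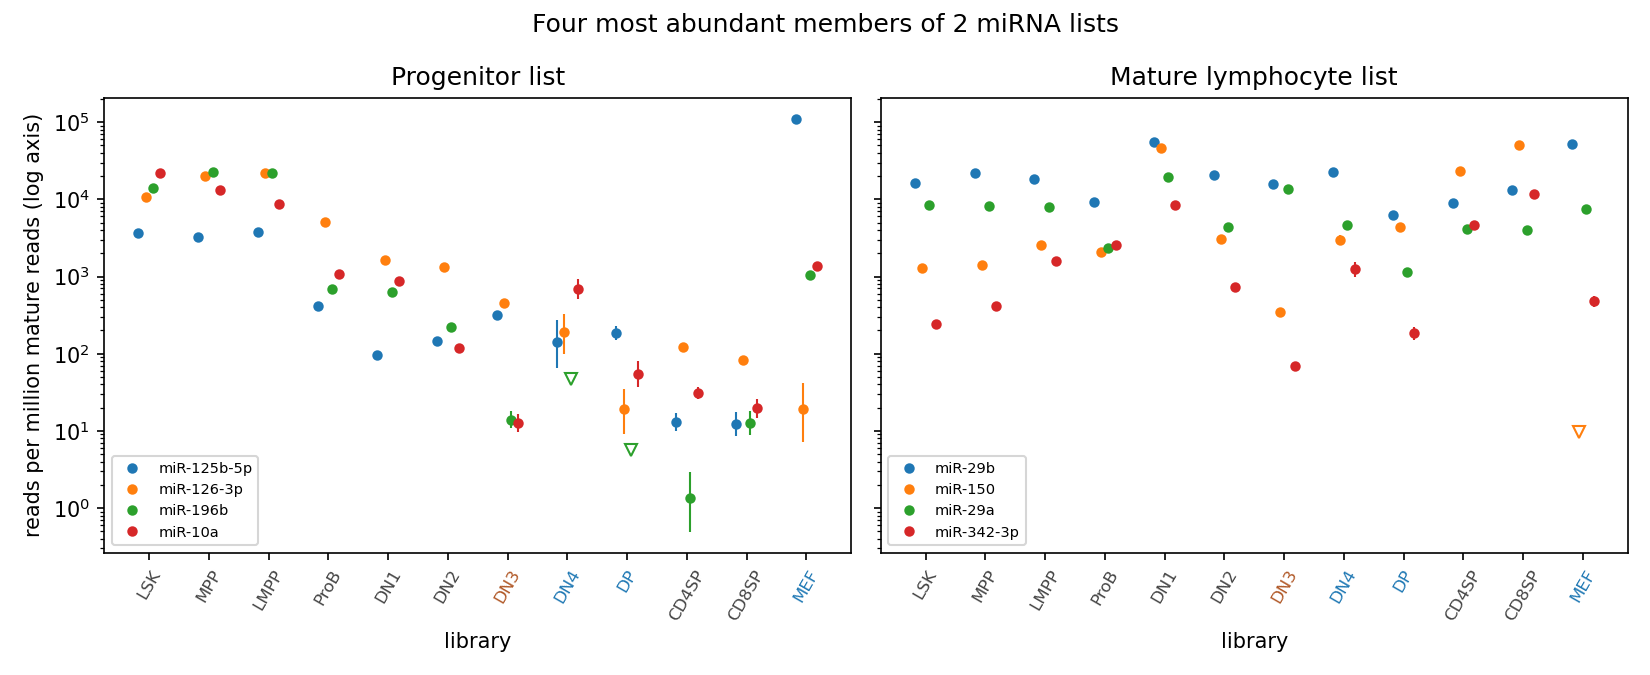
RPM (log axis) of the 4 members of highest mean of the progenitor list (left) and the mature lymphocyte list (right) in the 12 libraries; points are values, lines exact 95% Poisson intervals and open triangles the floor of 3 counts for a count of 0, and library names are grey, blue or brown for reads from base 3, 2 or 1. miR-196b was at 21851 RPM in LMPP and at 635.1 in DN1.

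From DN1 to DN2 the cells gain CD25; both libraries have reads from base 3. The miR-17 cluster and its paralogs were higher in DN2 for 15 of 18 measured members (median log2 ratio 1.34, percentile 100), among them miR-20b (2.89-fold, 2.84 to 2.94), miR-106a (2.88-fold, 2.83 to 2.94), miR-17 (2.87-fold, 2.83 to 2.91) and miR-20a (2.67-fold, 2.65 to 2.69). miR-128 was 9.49-fold higher (9.21 to 9.77) and miR-130b 2.82-fold (2.76 to 2.88). In the miR-181 family 3 of 5 members were higher (median log2 ratio 1.42, percentile 99.2), with miR-181d at 3.55-fold (3.44 to 3.67), miR-181b at 2.67-fold (2.62 to 2.73) and miR-181a-1* the other. Of the mature lymphocyte list 8 of 9 members were lower (median log2 ratio -3.18, percentile 0.005). miR-146a was 16.4-fold lower (15.4 to 17.4), miR-150 15-fold (14.7 to 15.3), miR-29c 11.4-fold (10.1 to 12.9), miR-342-3p 11.3-fold (10.8 to 11.9) and miR-29a 4.45-fold (4.36 to 4.54). The myeloid miR-223 was lower with them, 20.3-fold (19.4 to 21.2), as were miR-22 (8.87-fold, 8.56 to 9.20), miR-139-5p (6.95-fold, 6.65 to 7.27) and both arms of miR-142. The epithelial miR-141 and miR-200c were at 36.1 and 37.3 RPM in DN2 against 290.7 and 253.8 in DN1. In the progenitor list 5 of 10 measured members were lower (median log2 ratio -0.89, percentile 1.03), namely let-7e, miR-10a, miR-125a-5p, miR-196b and miR-99b. Of 139 miRNAs, 29 were higher and 24 lower in DN2. Size factors shifted all log2 ratios by -0.17, TMM factors by -0.13 and the total without the 3 most abundant miRNAs by 0.16, with which miR-142-3p (2.01-fold lower) did not pass the rule. Nor did let-7e, miR-125a-5p, miR-196b or miR-99b with the libraries thinned to the shallowest.

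DN3, in which T cell receptor beta selection takes place, was compared with DN2 and, as T against B lineage precursors, with ProB; it is the only library with reads from base 1, so that neither comparison can be separated from the read start. miR-181a was at 93133 RPM in DN3 against 25500 in DN2. The miRNAs highest over DN2 in the mature tables had smaller ratios with both tables added. These were 48.6 for miR-23a (44.1 to 53.8; 1249 in the mature tables), 18.3 for miR-23b (17.2 to 19.4; 341.2), 66.7 for miR-652 (57.1 to 78.3; 126.1), 4.92 for miR-669a (4.57 to 5.30; 29.01) and 2.24 for miR-378 (2.18 to 2.31; 21.7). miR-500 was 19.7-fold higher (16.7 to 23.5). miR-140* was 16.4-fold higher in the mature tables, and miR-140 as a whole had a ratio of 1.62 with both. miR-92a turned from 10.3-fold higher (9.95 to 10.7) to 2.87-fold lower with both tables added. Lower than in DN2 were miR-150 (8.88-fold, 8.41 to 9.38), miR-25 (5.80-fold, 5.71 to 5.90), miR-221 (4.07-fold, 3.89 to 4.25), miR-126-3p (2.90-fold, 2.75 to 3.07), miR-21 (2.51-fold, 2.49 to 2.52) and miR-130b (2.37-fold, 2.32 to 2.42). Of the progenitor list 6 of 10 members were lower than in DN2 and 2, let-7e and miR-99a, higher (median log2 ratio -1.78, percentile 0.02). Erythroid miRNAs summed to 4652 RPM in DN3 and 569.3 in DN2, with miR-486 alone at 92.9 and 124.1, and mesenchymal ones to 4246 and 2328. The myeloid miR-223 was lower, at 65.2 RPM in DN3 and 869.3 in DN2. From DN2 to DN3, 52 of 163 miRNAs were higher and 23 lower, or 30 and 20 without miRNAs mostly in the hairpin table, an alternative chosen after seeing the data. Size factors shifted all log2 ratios by -0.38, TMM factors by -0.32 and the total without the 3 most abundant miRNAs by -0.24. let-7e passed the rule with none of the 3, nor with unique assignments (1.01-fold), perfect matches (1.06-fold lower) or thinning to the shallowest library, which also ended the call of miR-130b.

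Against ProB, DN3 was low in miR-139-5p (438.6-fold, 402.8 to 478.5), miR-10a (84.2-fold, 64.9 to 111.2), miR-146a (81.2-fold, 67.7 to 97.47), miR-342-3p (36.9-fold, 33.0 to 41.4), miR-351 (14.2-fold, 12.7 to 16) and miR-126-3p (11.2-fold, 10.7 to 11.8). It was high in miR-31 (344.7-fold, 227.6 to 550.3) and the red-cell miR-451 (83.1-fold, 70.0 to 99.4), with miR-486 at 92.9 RPM against 24.6. miR-23a, miR-23b, miR-652 and miR-669a were 22.2-fold, 22.9-fold, 88.9-fold and 7.41-fold higher with both tables added, against 857.0-fold, 568.6-fold, 218.6-fold and 50.2-fold in the mature tables. miR-140* was 25.2-fold higher in the mature tables, and miR-140 as a whole had a ratio of 1.70 with both. The Sfmbt2 repeated cluster, whose members share reads and are uncertain one by one, had 9 of 13 measured members higher than in ProB and 8 of 13 higher than in DN2. Of 166 miRNAs, 59 were higher and 30 lower in DN3 than in ProB, or 34 and 28 without miRNAs mostly in the hairpin table. Size factors (shift of -0.40) gave 50 and 41, TMM factors (-0.53) gave 51 and 44, and the total without the 3 most abundant miRNAs shifted all log2 ratios by -0.11.

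DN3 and DN4 flank the loss of CD25 and differ in read start as well. miR-146a was 53.7-fold higher in DN4 (40.4 to 70.7), miR-22 29.8-fold (28.0 to 31.6), miR-423-5p 24.9-fold (23.7 to 26.3), miR-423-3p 20.3-fold (19.0 to 21.7), miR-342-3p 17.9-fold (13.8 to 22.9), miR-210, known from hypoxia, 14.1-fold (10.8 to 18.1) and miR-671-5p 13.4-fold (12.1 to 14.7). miR-92a* was 33.6-fold higher (26.5 to 42.4) in the mature tables, but miR-92a as a whole had a ratio of 1.06 with both tables added. Lower in DN4 were miR-16 (34.3-fold, 30.1 to 39.2), miR-155 (26.0-fold, 14.1 to 54.2), miR-21 (21.7-fold, 18.3 to 26.0) and miR-27a (18.4-fold, 9.66 to 40.1; 6.27-fold for miR-27a as a whole with both tables). miR-23a and miR-23b had 0 reads in DN4 and were 120.4-fold and 98.7-fold lower there with DN4 at the floor. With both tables added they were 16.6-fold and 133.5-fold lower. The miR-23, miR-27 and miR-24 clusters were lower for 5 of 6 measured members (median log2 ratio -3.68, percentile 0.805), miR-15 and miR-16 for 3 of 4 (-2.91, percentile 1.585) and the miR-30 family for 4 of 8, while miR-27a* and 2 star arms of the miR-30 family, miR-30b* and miR-30c-1*, were higher. The Sfmbt2 repeated cluster was lower for 11 of 12 members (-2.72, percentile 0.17). Its miR-669a had 0 reads in the mature table of DN4 and was 23.6-fold lower with DN4 at the floor. With both tables the ratio of miR-669a to DN3 was 0.0141 (0.00228 to 0.0679). In the same cluster miR-467e was 71.7-fold lower (12.9 to 2832), from 1 read in DN4. With both tables the ratio of miR-467e to DN3 was 0.0220 (0.00266 to 0.0795). Erythroid miRNAs summed to 552.2 RPM in DN4 and mesenchymal ones to 1152, against 4652 and 4246 in DN3. Of the erythroid ones miR-451 was at 394.4 in DN4 against 4258 in DN3, but miR-486 was at 126.2 against 92.9. Of 173 miRNAs, 63 were higher and 48 lower in DN4, the shallowest library. The split was 36 and 80 with TMM factors (shift of -0.94), 41 and 70 with size factors (-0.70), and 51 and 62 without the 3 most abundant miRNAs (-0.44). miR-30b* and miR-30c-1* passed the rule with neither TMM nor size factors, and miR-30c-1* not with perfect matches or thinning to the shallowest library.

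DN4 and DP, which share reads from base 2, flank the gain of CD4 and CD8. miR-181a was 2.52-fold higher in DP (2.48 to 2.56), at 553104 against 219599 RPM, and was the 1 miRNA that was higher, while 74 were lower. Furthest below DN4 were miR-146a (15.2-fold, 10.7 to 21.9), miR-92a* (11.1-fold, 8.27 to 15; 6.90-fold for miR-92a with both tables), miR-21* (10.9-fold, 7.43 to 15.9; 4.82-fold for miR-21 with both), miR-298 (9.55-fold, 8.14 to 11.2), miR-296-3p (9.10-fold, 8.33 to 9.95), miR-29c (7.38-fold, 5.76 to 9.54), miR-342-3p (6.80-fold, 4.99 to 9.26) and miR-7a (5.50-fold, 4.95 to 6.12). With size and TMM factors miR-29c was 2.48-fold and 2.13-fold, miR-342-3p 2.29-fold and 1.96-fold and miR-7a 1.85-fold and 1.59-fold lower, and none of them passed the rule. The miR-181 family, with miR-181a higher and miR-181d lower (1.25-fold and 1.45-fold higher with size and TMM factors), had a median log2 ratio of 0.17, at percentile 99.2 of matched lists, and medians of 1.74 with size factors, 1.96 with TMM factors and -0.00177 with the more abundant arm only. The let-7 family, lower for 5 of 9 members with a median log2 ratio of -1.17, had medians of 0.62 with TMM factors and 0.40 with size factors. The miR-17 cluster and its paralogs were lower for 15 of 18 members (median log2 ratio -1.75), and their median was 0.04 with TMM factors and -0.18 with size factors. In DP erythroid miRNAs summed to 19.1 RPM and mesenchymal ones to 217.6, against 552.2 and 1152 in DN4. TMM factors (shift of 1.79) gave 24 higher and 10 lower, and size factors (1.57) 20 and 10. The total without the 3 most abundant miRNAs, which are miR-16, miR-20a and miR-21 over all libraries and not miR-181a, gave 1 and 74.

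What changes at the end of thymic development was asked by setting DP against both single-positive populations, which have other read starts. miR-16 was 88.3-fold higher in CD4SP (83.9 to 93) and 72.1-fold in CD8SP (68.5 to 75.9). The activation-linked miR-155 was 113.01-fold (75.9 to 176.4) and 96.7-fold higher (64.9 to 150.9), and miR-21 61.5-fold (54.7 to 69.4) and 49.9-fold (44.4 to 56.3). miR-181a was 13.0-fold lower in CD8SP than in DP (12.9 to 13.1), miR-128 12.3-fold (11.9 to 12.7; 6.66-fold with both tables), miR-19b 12.1-fold (11.5 to 12.8) and miR-19a 11.1-fold (9.52 to 13.0). miR-671-5p was 81.8-fold lower in CD4SP (67.7 to 99.5) and 61.1-fold in CD8SP (49.5 to 76.1; 28.8-fold for miR-671 as a whole with both tables), and miR-378 63.3-fold (59.0 to 68.0) and 29.6-fold (27.7 to 31.5; 3.43-fold for miR-378 as a whole with both tables). miR-24 was 56.7-fold (51.5 to 62.5) and miR-27a 45.2-fold higher in CD8SP (35.1 to 59.2; 28.4-fold for miR-27a as a whole with both tables). From DP to CD4SP the activation list was higher for 4 of 5 members (median log2 ratio 5.94, percentile 99.945), miR-15 and miR-16 for 4 of 4 (3.78), the miR-30 family for 4 of 4 (3.31) and the Sfmbt2 repeated cluster for 7 of 8 (4.29, percentile 99.96). The exception in the activation list was miR-146b, which was lower, but did not pass the rule without the 3 most abundant miRNAs (2.21-fold) or with the libraries thinned to the shallowest. Mesenchymal miRNAs summed to 2623 RPM in CD4SP and 2788 in CD8SP against 217.6 in DP. Most of these sums was miR-322, at 2140, 2332 and 152.7. Erythroid miRNAs summed to 44.9 RPM in CD4SP and 620.6 in CD8SP against 19.1 in DP. In CD4SP 64 miRNAs were higher and 48 lower (78.9% of those tested), and in CD8SP 76 and 43 of 152. The total without the 3 most abundant miRNAs shifted all log2 ratios by 0.53 for CD4SP and 0.45 for CD8SP, and size and TMM factors shifted those for CD8SP by -0.10 and -0.12.

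Because of the read starts, both populations were also set against DN2, the nearest earlier thymic stage with reads from base 3, a comparison chosen after seeing the data. The mature lymphocyte miR-150 was 7.52-fold higher in CD4SP (7.34 to 7.70) and 16.1-fold in CD8SP (15.8 to 16.5), miR-342-3p 6.35-fold (6.05 to 6.67) and 16.02-fold (15.3 to 16.8), and miR-22 9.28-fold (8.95 to 9.62) and 5.32-fold (5.12 to 5.53). Epithelial miRNAs summed to 256.8 RPM in CD4SP and 414.2 in CD8SP, against 133.6 in DN2. The activation list had median log2 ratios of -0.09 in CD4SP (percentile 60.6) and -0.21 in CD8SP (percentile 40.3), or 0.47 and 0.18 with size factors. miR-21 was at 112534 RPM in DN2 against 33005 in CD4SP and 26776 in CD8SP. miR-16 was at 156103 against 246177 and 200991, and miR-155 at 3436 against 5177 and 4429. Medians of miR-15 and miR-16 were 0.63 and 0.33, of the miR-30 family 0.50 and 0.30 and of the Sfmbt2 repeated cluster 1.52 and 1.59. The miR-17 cluster and its paralogs were lower for 13 of 18 members in CD4SP (median log2 ratio -1.43, percentile 0.15) and 9 of 18 in CD8SP (-1.18, percentile 0.155). miR-221 was 22.1-fold lower in CD4SP (20.2 to 24.2) and 11.8-fold in CD8SP (10.8 to 12.9). It belongs to the progenitor list, of which 7 of 9 measured members were lower in CD4SP (median log2 ratio -3.49) and 7 of 10 in CD8SP (-3.57), where the other 3, let-7e, miR-125a-5p and miR-99b, were higher, though none of them with the libraries thinned to the shallowest. Both arms of miR-142 were higher in both populations, but miR-142-5p did not pass the rule in CD4SP without the 3 most abundant miRNAs (1.98-fold). miR-182 and miR-183, the measured members of the miR-183 cluster, were higher in CD4SP, and 3 of 3, with miR-96, in CD8SP (median log2 ratio 3.83, percentile 99.495). With the libraries thinned miR-183 passed the rule in neither population and miR-96 not in CD8SP, and without sequences seen once miR-183 did not in CD4SP. miR-181a was 3.84-fold higher in CD4SP (3.81 to 3.88) and miR-181d 4.03-fold lower (3.90 to 4.16), and the family's median log2 ratio there was -0.42, but 0.15 with size factors and 0.04 with TMM factors. miR-26b was 2.45-fold higher in CD8SP, but not past the rule with both tables added (1.65-fold), without the 3 most abundant miRNAs (2.07-fold) or with the libraries thinned. From DN2 to CD4SP 20 miRNAs were higher and 49 lower (48.6% of those tested), and from DN2 to CD8SP 29 and 33 of 149. TMM factors gave 42 and 33 for CD4SP (shift of 0.46) and 48 and 24 for CD8SP (0.41), and size factors 50 and 31 (0.56) and 47 and 23 (0.39). Without the 3 most abundant miRNAs CD8SP gave 23 and 45, at a shift of -0.24, and for CD4SP the shift was -0.16.

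CD4SP and CD8SP, with the same read start, had a Spearman correlation of 0.98 across 276 miRNAs, which are not independent replicates. The miR-23, miR-27 and miR-24 clusters were higher in CD8SP for 3 of 4 measured members (median log2 ratio 1.84, percentile 99.87), with miR-27a at 4.81-fold (4.65 to 4.97), miR-24 at 2.65-fold (2.63 to 2.68) and miR-27a* the other. miR-342-3p was 2.52-fold higher (2.48 to 2.57), miR-324-5p 2.53-fold (2.39 to 2.67) and miR-150, a miRNA of mature lymphocytes, 2.15-fold (2.13 to 2.16). The miR-181 family was lower for 3 of 5 members (median log2 ratio -1.20, percentile 0.02), miR-181b 2.44-fold (2.38 to 2.51), miR-181a 2.30-fold (2.29 to 2.32) and miR-181a-1* 2.63-fold (2.43 to 2.86). The other 2 lower ones were miR-128 (2.09-fold, 2.03 to 2.15) and miR-15b* (2.22-fold, 2.05 to 2.41); miR-181a-1* and miR-15b* were named after their values were seen. Markers of other cells were also higher in CD8SP, with miR-223 at 202.98 RPM against 6.45, miR-451 at 445.4 against 32.9 and miR-486 at 140.6 against 11.1. In all, 15 miRNAs were higher and 5 lower in CD8SP, 15.2% of those tested, and size factors shifted all log2 ratios by -0.18, with which miR-150 (1.90-fold) did not pass the rule. Nor did miR-128, miR-181b, miR-181a-1*, miR-324-5p, miR-27a* or miR-15b* with the libraries thinned to the shallowest, or miR-15b* with perfect matches.

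**Figure D3:**
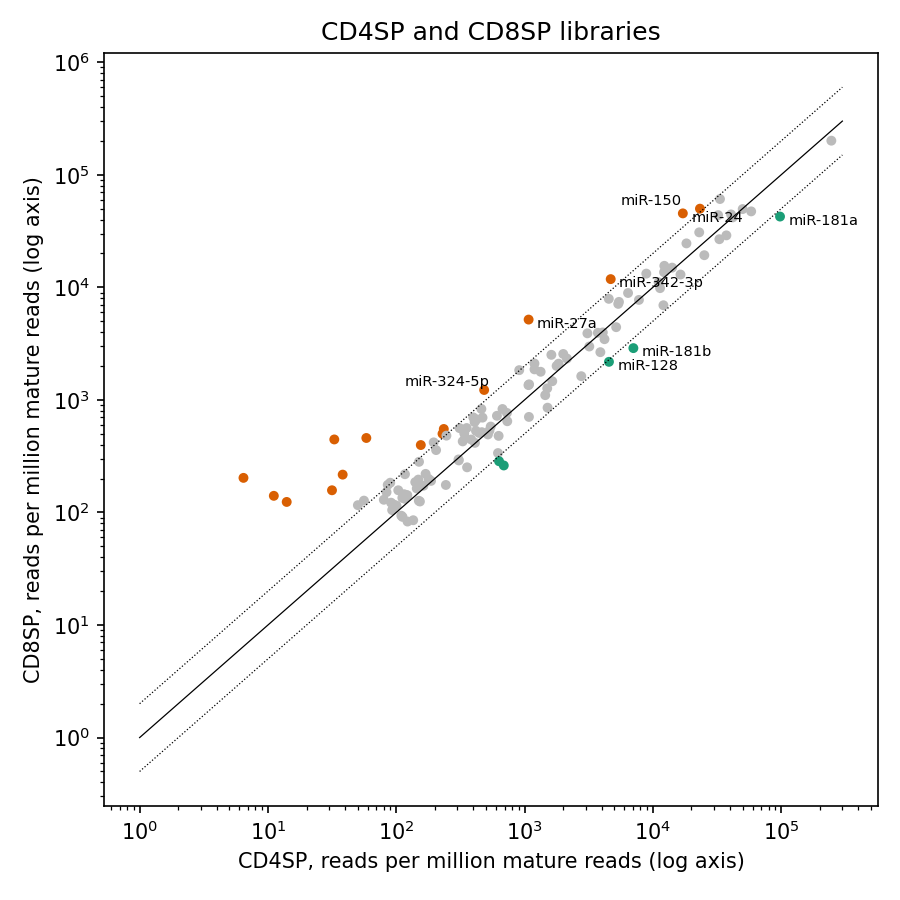
RPM in CD4SP (x, log axis) and CD8SP (y, log axis) for the miRNAs tested; orange points are higher and green points lower in CD8SP by the rule, the solid line is equality and the dotted lines are 2-fold. miR-27a was at 1076 RPM in CD4SP and 5173 in CD8SP.

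Marrow and thymus were compared by asking for how many miRNAs every marrow library lay on 1 side of every thymus library. In marrow miR-130a ran from 611.9 to 9621 RPM, against at most 189.2 in the thymus, and miR-126-3p from 5160 to 21752 against at most 1632. miR-322 ran from 5158 to 11630 in marrow and to 2332 at most in the thymus. miR-142-3p was at least 6071 in every thymus library and at most 5225 in marrow. Such a parting held for 24 miRNAs (10.9% of those tested), 18 higher in marrow and 6 higher in thymus, and without ProB 43 were higher in marrow and 9 in thymus. Chance gives 0.606% when all orders are alike, an assumption that developmental stages do not meet. Among the 8 libraries with reads from base 3 it held for 39 of 180 (21.7%, chance 2.86%), 28 higher in marrow and 11 in thymus.

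Over the 7 thymic stages miR-223 was at 17609 RPM in DN1, 2731-fold above CD4SP (1901 to 4078) and 9225-fold above DP (1656 to 364367), which had 1 read. DN4 had 0 reads of it, and DN1 was 372.05-fold above the floor of DN4 (lower limit 302.6). Wide ranges were also those of miR-139-5p (1602-fold, 443.4 to 13229, DN1 over DP, which had 2 reads), miR-451 (446.2-fold, 191.2 to 1374, DN3 over DP), miR-296-3p (433.97-fold, 369.03 to 512.9, DN4 over CD4SP) and miR-467c (379.7-fold, 105.1 to 3136, CD4SP over DP, which had 2 reads). The lowest stage was also chosen after zeros were set to the floor, an alternative added after seeing the data. Then miR-23a, miR-23b and miR-669a joined them, each DN3 over DP in the mature tables. The range was 2986-fold for miR-23a (535.9 to 117944) and 586.4-fold for miR-669a (105.2 to 23163), each from 1 read in DP. That of miR-23b, with 0 reads in DP, was 815.8-fold with DP at the floor (lower limit 663.4). In DP 98.5%, 100% and 84.6% of the reads of these 3 lay in the hairpin table. miR-21, miR-671-5p, miR-146a and miR-378 had ranges of 296.7-fold to 223.4-fold, and miR-32 had a range of 192.6-fold (65.8 to 934.1, DN1 over DP, which had 3 reads). Within the 4 stages with reads from base 3 the widest, after that of miR-223, were those of miR-139-5p (26.0-fold, 24.5 to 27.7), miR-221 (22.1-fold, DN2 over CD4SP) and miR-126-3p (19.6-fold, 17.2 to 22.6, DN1 over CD8SP). Of 195 miRNAs, 177 (90.8%) had a range of 4-fold or more over all 7 stages, and for 175 of them the highest or lowest stage was DN3, DN4 or DP, the stages with other read starts. Over the 4 stages the count was 60 of 151 (39.7%).

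MEF was compared with the blood cells as the only sample of another tissue. miR-483, within an intron of Igf2, was at 5692 RPM (5429 to 5964) and 360.8-fold above the highest blood library, DN4, a ratio with an interval of 64.7 to 14258 because DN4 had 1 read. Of the Dlk1-Dio3 locus 18 of 29 measured members were higher, and the locus summed to 65616 RPM in MEF (64716 to 66526) against 659.1 in LSK, the highest blood library. Among them miR-127 was 151.05-fold higher (134.4 to 170.4). The nearest library was DN4 with 0 reads for miR-134, miR-382 and miR-431. With DN4 at the floor these were 115.4-fold, 106.5-fold and 82.96-fold higher, with lower limits of 93.7, 86.5 and 67.4. For miR-341 the nearest was DN4 with 1 read (102.1-fold, 18.2 to 4039). miR-125b-3p, also with 0 reads in DN4, was 101.5-fold higher with DN4 at the floor (lower limit 82.4). miR-100 was 76.4-fold higher (61.3 to 97.7). Of the mesenchymal miRNAs 7 of 14 were higher, with miR-143 at 15929 RPM against at most 344.2. miR-142-5p was 810.5-fold lower than the lowest blood library (280.3 to 8370), from 2.5 reads in MEF after shared reads were split. miR-15a was 25.7-fold lower (18.5 to 36.5), miR-15b 21.5-fold (14.45 to 33.4), miR-106b 16.6-fold (9.63 to 33.3) and miR-16 15.1-fold (11.6 to 20.04). miR-150 and miR-20b had 0 reads in MEF and, with MEF at the floor, were 35.9-fold and 35.6-fold lower (lower limits 29.2 and 28.6). miR-106a, with 0.333 of a shared read, was 75.7-fold lower with MEF at the floor (lower limit 61.2). In all, 43 miRNAs exceeded the highest of the 11 blood libraries more than 4-fold and 22 lay more than 4-fold below the lowest, or 75 and 12 with size factors. Against DN4 and DP alone, which share the read start of MEF, the counts were 63 and 33.

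Markers of cell types that a sort could hold were read in every library. The myeloid miR-223 was highest in DN1 (17609 RPM) and LMPP (10296) and at 1.91 in DP, with 0 reads in DN4 (up to 47.3 RPM). The erythroid miRNAs summed to 4655 in LMPP, 4652 in DN3 and 19.1 in DP, with miR-486 alone at 1054, 92.9 and 7.64. The liver miR-122 was at 1163 in LSK, 1234 in MPP and 4313 in LMPP and at most 28.6 in the other libraries. Endothelial and stem-cell miR-126 summed to 23440 in LMPP. Mesenchymal miRNAs summed to 33513 in MEF, 11337 in LSK, 14393 in MPP, 10105 in LMPP and 6664 in ProB, and in the thymus to between 217.6 in DP and 4246 in DN3. Most of the marrow sums was miR-322, at 7998 in LSK, 11630 in MPP, 7753 in LMPP and 5158 in ProB against 288.3 in MEF, while miR-143, at 15929 in MEF, was at 40.9 in LSK, 40.5 in MPP, 344.2 in LMPP and 2.74 in ProB. In the thymus miR-322 was at 1630 in DN1, 1160 in DN2, 881.1 in DN3 and 189.3 in DN4. It was at 152.7 in DP, 2140 in CD4SP and 2332 in CD8SP. In DN3 miR-31, also of this group, was at 2989 with both tables added. Epithelial miRNAs were highest in DN1 (801.2), muscle miRNAs in MEF (162.0) and neural miRNAs in MEF (58.3).

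Arms and ends were read for the 20 most abundant miRNAs. The share of reads from the 5p or unstarred arm of miR-17 was 90.7% in LSK and 77.0% in DN3, but 21.3% in DN4, 18.4% in DP and 13.5% in MEF. That of miR-21 was at least 98.9% in the 9 libraries with reads from base 1 or 3, and 66.2% in DN4, 84.6% in DP and 58.0% in MEF. For miR-142 it ran from 50.1% to 87.9% in those 9 libraries and was 8.76% in DN4, 7.67% in DP and 4.17% in MEF, the last from 48 reads. Reads with another 5' end than the most common were under 5% of reads for 18 of the 20 miRNAs in every library; they reached 47.8% for miR-142-5p and 15.6% for miR-142-3p. The share of reads in the hairpin table ran from 6.28% in MEF (6.20 to 6.37) to 15.4% in LMPP (15.3 to 15.5).

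**Figure D4:**
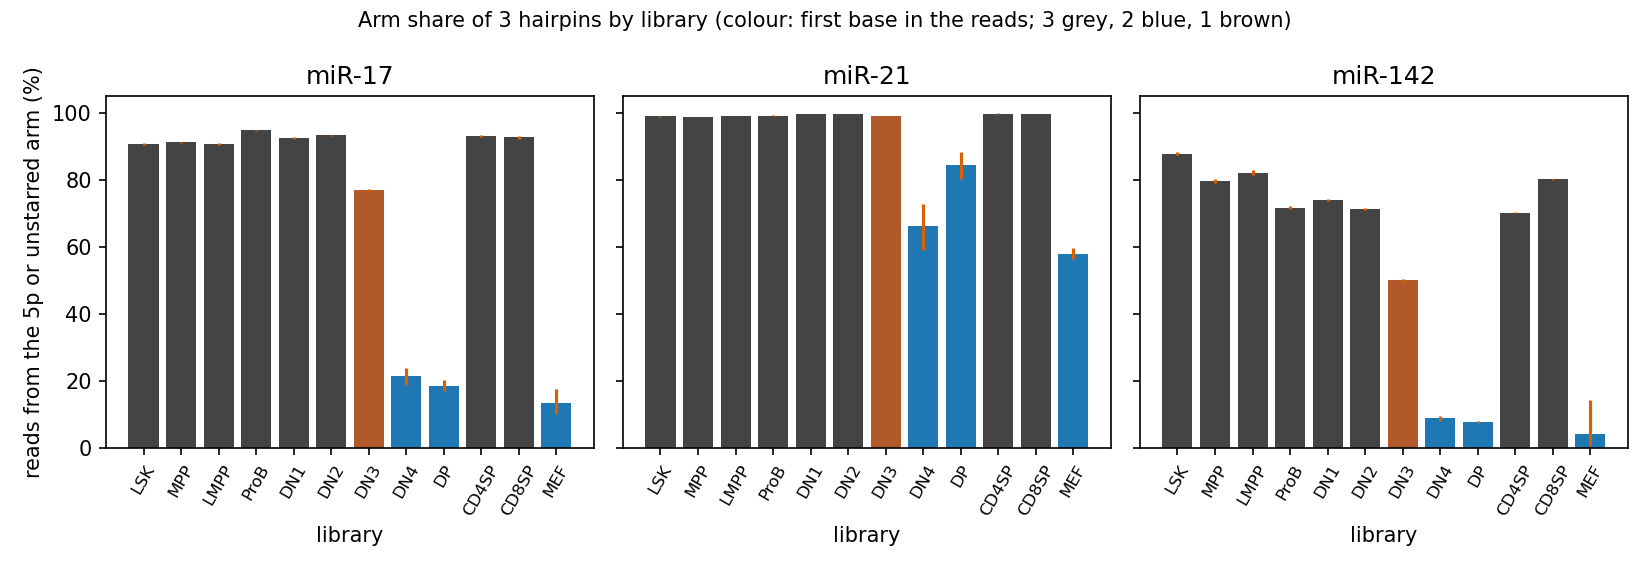
Share of mature reads from the 5p or unstarred arm (%) of the miR-17, miR-21 and miR-142 hairpins in the 12 libraries, with exact 95% binomial intervals; grey, blue and brown bars have reads from base 3, 2 and 1. For miR-17 the share was 13.5% to 21.3% in DN4, DP and MEF.

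Positions are those of GENCODE M21 hairpins on mouse GRCm38. Mir196b lies on chromosome 6 (52230081 to 52230165, minus strand) within an exon of Hoxa9. Mir139 lies on chromosome 7 (101475376 to 101475443) within an intron of Pde2a and Gm45837, and Mir150 on chromosome 7 (45121757 to 45121821) between annotated genes on its strand. miR-181a matches Mir181a-1 on chromosome 1 (137966455 to 137966541), within an intron of Gm4258, and Mir181a-2 on chromosome 2 (38852735 to 38852810), between annotated genes on its strand, and its reads cannot be assigned to either. miR-128 matches Mir128-1 within an intron of R3hdm1 (chromosome 1, 128202361 to 128202430) and Mir128-2 within an intron of Arpp21 (chromosome 9, 112118636 to 112118711). Mir223 lies on chromosome X within an exon of F630028O10Rik (96242817 to 96242926), Mir342 on chromosome 12 within an intron of Evl (108658620 to 108658718), Mir126a on chromosome 2 within an exon of Egfl7 (26591357 to 26591429), Mir20a on chromosome 14 within an exon of Mir17hg (115044157 to 115044263) and Mir27a on chromosome 8 between annotated genes on its strand (84208672 to 84208758).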

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

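No explanation of these results was tested. No group holds more than 1 library, so no sample could be compared with others of its group. The signals below exceed the 3 counts that a count of 0 allows in at least 1 library. Sequences of the opposite strand were sought in the mature and hairpin tables together, so some lie within the counts compared. In CD4SP, with only a mature table here, these were 131 reads for let-7a and 62 for miR-34a. Reads of sequences that match only the strand opposite to a hairpin numbered 1191 for miR-1895, 615 for let-7a, 457 for miR-34a, 62 for let-7b, 59 for miR-142 (all of its reads in DN3), 47 for miR-10a, 31 for miR-1935, 29 for miR-1946b, 22 for miR-690, 21 for miR-709, 14 for miR-466i, 13 for miR-1186, 11 for miR-1937b, 8 each for miR-10b and miR-1196, and 5 for let-7c (all of its reads in DN3), summed over the libraries. Names found in the hairpin tables and in no mature table were miR-1928 with 4699 reads (3525 of them in DN3), miR-1895 with 1244, miR-669i with 243, miR-669j with 129, miR-715 with 62, miR-696 with 22, miR-703 with 8, miR-698 with 7 and miR-1197 with 6. The 1244 reads of miR-1895 include its 1191 of the opposite strand, so these are largely the same signal.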

How the results depend on the processing

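The libraries with reads from base 3 alone, the comparisons of DN2 with CD4SP and CD8SP, MEF against DN4 and DP, the lowest thymic stage with zeros at the floor, and leaving out miRNAs mostly in the hairpin table were chosen only after the results were seen. No paired analysis was possible because each population has 1 library. The shallow DN4 (63386 reads) and MEF limit what could be called there. Of the counts recomputed in each direction 99 moved by over 1.5 times from the reported one and the others did not; the cause was not tested, except that another rule, floor or depth changes which miRNAs can pass. Counts below are of miRNAs higher or lower in the second library, with the reported count in parentheses at first mention. With a floor of 10 RPM and with none, LSK to MPP gave 10 and 14 lower (3), MPP to LMPP 43 and 43 higher (21), LMPP to ProB 104 and 104 lower (48), LMPP to DN1 23 and 25 higher (15) and 110 and 110 lower (60), ProB to DN3 1.1e+02 (rounded to 2 digits) and 118 higher (59) and 46 and 49 lower (30), DN1 to DN2 41 and 45 lower (24), DN2 to DN3 88 and 98 higher (52), DN2 to CD4SP 31 and 31 higher (20) and DN2 to CD8SP 50 and 50 lower (33). At 1.5-fold LSK to MPP gave 11 higher (0) and 10 lower, MPP to LMPP 4 lower (2), LMPP to ProB 27 higher (12), DN1 to DN2 44 higher (29), DN4 to DP 2 higher (1), CD4SP to CD8SP 34 higher (15) and 9 lower (5), DN2 to CD4SP 34 higher and DN2 to CD8SP 46 higher (29). At 4-fold MPP to LMPP gave 4 higher and 0 lower, LMPP to ProB 6 and 31, LMPP to DN1 8 and 29, ProB to DN3 17 lower, DN1 to DN2 3 and 15, DN2 to DN3 33 and 9 (23 lower), DN3 to DN4 39 and 25 (63 and 48), DN4 to DP 0 and 18 (74 lower), CD4SP to CD8SP 8 and 0, DN2 to CD4SP 8 and 18 (49 lower) and DN2 to CD8SP 12 and 13. Thinned to the shallowest library, MPP to LMPP gave 9 higher and 1 lower, LMPP to ProB 28 lower, LMPP to DN1 9 and 31, ProB to DN3 19 lower, DN1 to DN2 16 higher, DN2 to DN3 12 lower, CD4SP to CD8SP 7 and 1, DN2 to CD4SP 8 and 25 and DN2 to CD8SP 11 and 16. Size factors gave 27 higher from LMPP to ProB, 25 higher and 36 lower from LMPP to DN1, 41 higher from DN3 to DN4, 20 and 10 from DN4 to DP, 50 and 31 from DN2 to CD4SP and 47 higher from DN2 to CD8SP. TMM factors gave 37 higher from LMPP to ProB, 27 and 34 from LMPP to DN1, 36 and 80 from DN3 to DN4, 24 and 10 from DN4 to DP, 42 higher from DN2 to CD4SP and 48 higher from DN2 to CD8SP. Without the 3 most abundant miRNAs LSK to MPP gave 5 lower. With both tables added it gave 1 higher, and MPP to LMPP 32 higher. Without miRNAs mostly in the hairpin table ProB to DN3 gave 34 higher and DN2 to DN3 30. miRNAs higher in marrow (18) numbered 16 to 43 when each library was left out in turn, with 43 without ProB, and those higher in thymus (6) 5 to 9; libraries with reads from base 3 gave 28 and 11. The thymic range count (177) was 60 over the 4 stages with reads from base 3 and moved by under 1.5 times with zeros at the floor. MEF (43 higher, 22 lower) gave 75 and 12 with size factors, 73 higher at 2-fold, and 28 and 10 at 8-fold. Of the log2 ratios of the miRNAs named by their ratio, up to 8 per direction, 913 stayed within their intervals, 690 moved with the same sign and 1 reversed. That was miR-92a from DN2 to DN3, at -1.52 with both tables and its arms added. Other miRNAs in the text were not among these, and some changed sign. Examples are miR-181d from DN4 to DP with size and TMM factors and let-7e from DN2 to DN3 with perfect matches. With a prior count or the more abundant arm only, 60 list medians moved by over 0.1, and of those at an extreme percentile 1 changed sign, that of the miR-181 family from DN4 to DP, at -0.00177 with the more abundant arm only; others changed sign at middle percentiles, and scaling changed the sign of further medians, such as let-7 from DN4 to DP. Of the correlations between libraries 18 moved by over 0.05 and 114 did not, and the 11 hairpin-table shares moved when taken over distinct sequences.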

Other observations

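The tests of explanations for the low miRNAs of DN4 and DP, for miR-122 and for DN1 were chosen only after the results were seen, and the split of the 8 libraries with reads from base 3 was added after the read starts were seen. miR-2142 was at 27109 RPM in LMPP with both tables added, against 113.7 in MPP, and 95.3% of its reads there lay in the hairpin table. DN3 held miR-451 at 4258 RPM with miR-144 at 301.1, while the neighbouring DN2 held 422.4 and 22.8, but miR-486 was at 92.9 in DN3 and 124.1 in DN2.

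A set of 15 miRNAs, miR-16, miR-15b, miR-20a, miR-21, miR-24, miR-26a, miR-26b, miR-27a, miR-30b, miR-30c, miR-32, miR-155, miR-322, miR-467c and let-7f, was at least 4-fold lower in both DN4 and DP than in any of the 9 libraries with other read starts. Reads moved to the hairpin table do not account for most of it, since 86.7% of the set stayed 4-fold lower with both tables added, nor do a few abundant miRNAs, since 80.0% stayed so with size factors. In MEF, an unrelated cell type, 100% of the set lay below the 9 libraries too, as did 61.4% of the other 70 miRNAs, but the bound for a shared way of preparing the libraries, more than double the share of the others, could not be reached, so this test decides nothing. Arm shares of 23 of 46 hairpins, 50%, were apart between DN4, DP and MEF and the 9 libraries (chance 0.909%), which did not exceed the bound of more than 50%. Library preparation and stage therefore cannot be told apart for DN4 and DP, because no other blood library has their read start.

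miR-122 was at 4313 RPM in LMPP. Red cells like those in 3 thymus libraries, DN1, DN2 and CD8SP, are argued against as its source. There miR-451 was 3.52, 3.40 and 3.17 times miR-486, near the 3.29 of LMPP. The ratio of miR-122 to miR-451 lay 132.4-fold, 158.4-fold and 134.1-fold below that of LMPP (lower limits from their own counts 87.3, 80.1 and 74.7). It lay 1212-fold below in DN3, where miR-451 was 45.8 times miR-486. In CD4SP, DN4 and DP it lay 14.2-fold, 31.1-fold and 3.11-fold below (lower limits 8.04, 5.10 and 0.51). In ProB, a marrow library that held 51.3 RPM of miR-451, it lay only 2.23-fold below, so red cells of the marrow stay open. From LSK to MPP the ratios of miR-122, miR-451 and miR-486 were 1.06, 1.31 and 0.382, the largest 3.42 times the smallest, so that a single outside source of all 3 in these libraries is argued against by miR-486 alone. From MPP to LMPP they were 3.49, 3.02 and 3.64, the largest 1.21 times the smallest, and a shared outside source may account for the higher values in LMPP. It stays open beside other sources of miR-122 and expression in the progenitors, which were not tested.

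DN1 was high in miR-150, miR-342-3p, miR-146a and miR-223. Mature thymocytes in the sort, which gated out CD4 and CD8, are argued against as the whole cause by miR-223 and miR-146a. To reach miR-150, 92.5% of CD8SP material would have to be mixed with DN2. That mixture would hold 253.2 RPM of miR-223 and 821.4 of miR-146a, against 17609 and 7079 in DN1. It would hold 10999 of miR-342-3p against 8362. In it miR-181a would be 3.15 times its DN1 value, but both DN2 (25500 RPM) and CD8SP (42560) lay above DN1 (13112). In miR-21 both DN2 (112534) and CD8SP (26776) lay below DN1 (159118). No mixture of CD8SP and DN2 therefore gives the whole DN1 profile. This decides nothing about a smaller share in another background, which was not tested. Mature thymocytes stay open as part of the cause for miR-150 and miR-342-3p. Pro-B cells are argued against because each of the 4 miRNAs was at least 3.23-fold higher in DN1 than in ProB. Myeloid and other lymphoid cells were not sampled, and they and expression in DN1 stay open.

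Random grouping with all orders alike would seldom give the count of miRNAs that part marrow from thymus. Related stages do not meet that assumption, so the splits do not exclude chance for them. Of 100 splits of the 11 libraries, the real one and others drawn at random, 1, the real one, gave 24. The highest other of those drawn, DN2, DN3, DN4 and DP against the rest, gave 22. Without ProB those higher in marrow numbered 43 in place of 18. In the libraries with reads from base 3, 1 of 35 splits, the real one, gave 39, and the highest other, LSK, MPP, LMPP and DN1 against the rest, gave 32.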
